A study of Rattus norvegicus with 6 samples.

How the data were processed

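RNA was sequenced from 6 libraries of H9c2 cells, a myoblast line derived from embryonic rat heart, written as Hc92 in one label. The sample titles put the libraries into 3 groups of 2: empty vector, BMPR2 tail domain mutant and BMPR2 kinase domain mutant. The labels name polyA RNA, column extraction and a standard Illumina preparation. They do not say whether the 2 replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

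The deposited values are raw read counts per Ensembl rat gene identifier, 1 file per library, with no normalization. Per the submitters' processing notes, the tools were Trimmomatic 0.33, STAR 2.4.0 and HTSeq 0.6.1p1, and the genome build was Rnor_5.0. The strand setting, the annotation release and any filters are not given in the sources used here. Without a known strand setting, reads of a gene and of its antisense partner are not distinguished here. Each file holds 26404 gene rows and 5 rows that name no gene. The latter were left out of library sizes and tests. Between 15.4% and 17.5% of the total over all rows lay in the row for reads in no annotated gene, and between 27.3% and 31.5% in the row for alignments that were not unique. Reads that did not align uniquely enter no gene's count, so genes with near-identical copies are under-counted.

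The files pair no identifier with a gene name. The rat gene table used here, of the GRCr8 assembly, gives an Ensembl identifier for 0 of its 47357 genes, so 0 identifiers matched a symbol. The consequences are these. Bmpr2 was not looked up in the libraries, so the labels were not checked against the targeted gene. None of the 29 gene lists fixed before the data were examined was tested. A check of GC content or gene length would be void, since 0 genes could be given a value. The rule for named genes, fixed beforehand, took genes with a symbol and therefore named none. In its place, at most 2 identifiers that fell and 2 that rose are printed: the smallest p per direction against empty vector in each mutant, and the smallest p among falls in the tail mutant against the kinase mutant. This replacement was set after the files had been examined.

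Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults by group (a minimum count of 10, scaled to library size, in the smallest group, and a total of at least 15), which left 12221 genes. Libraries were scaled by TMM, dispersions were estimated robustly, and each comparison was a contrast in a quasi-likelihood model with group as the only term. For each gene all 6 libraries shared 1 estimate of the spread with 3 residual degrees of freedom. That estimate was moderated across genes, with a median of 3.25 prior degrees of freedom, so each test also rests on the spread of other genes. P-values were adjusted by Benjamini-Hochberg and called below 0.05. The common biological coefficient of variation was 28.1%. Levels are given as CPM scaled by TMM, with SD over 2 libraries. The standard error of a log2 fold change is its size divided by the square root of its F value.

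A second measure needs no model and was added after the data were examined. It counts genes whose lowest CPM in one set of libraries was at least 1 and at least 8 times the highest CPM in the other set. A count under 3 was raised to 3, so each such fold is a lower bound. The floor of 3 counts corresponds to between 0.111 and 0.149 CPM per library. The floor covers counting error only.

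The total count in genes ranged from 19116082 to 24936136 per library. At that depth counting error is small beside the spread between replicates: over tested genes, the mean chi-square per gene between replicates was 63.9 in empty vector, 187 in the tail mutant and 93.2 in the kinase mutant, where sampling noise alone gives about 1. No 2 libraries were therefore treated as one.

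The fits were tested on simulated data. In 5 draws with the real means, library sizes and tagwise dispersions, 200 genes were changed in each mutant. For the tail mutant against empty vector, over 12221 genes, edgeR recovered 12.8% of genes changed 2-fold, 71.2% of those changed 4-fold, 84% of those changed 8-fold and 92.8% of those changed 64-fold, and 9.94% of its calls were false. The shares for the kinase mutant were 14%, 74.8%, 84.8% and 95.2%, with 8.82% false. DESeq2 1.42.0 recovered more 2-fold changes (30.4% and 32.4%), but 27.3% and 25.5% of its calls were false. For limma-voom, in limma 3.58.1, 6.7% and 7.73% of calls were false. The simulated replicates differed gene by gene and independently, so these shares do not describe replicates that differ in many genes together. They also rest on 200 changed genes per mutant, most by 4-fold or more, which makes the Benjamini-Hochberg threshold easier to pass. In the real fits edgeR called 1 gene against empty vector in each mutant. The shares therefore do not tell how many changes of a given size the real fits would call.

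Both mutants were compared with the same 2 empty vector libraries, which makes their fold changes alike by chance. In 50 simulated sets with no difference between groups, drawn independently for each gene, the same overlap and correlation were computed. A split of the controls would leave 1 library in each part and was not made. As alternatives, DESeq2, limma-voom, RLE size factors, no count filter, a stricter filter (CPM of at least 1 in at least 2 libraries and a mean count of at least 20), only the 4 libraries compared, the replicate number as a block, a test against 1.2-fold and the omission of each library were run.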

Results

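Gene expression was measured by polyA RNA sequencing in the rat cardiac myoblast line H9c2. The groups were empty vector, BMPR2 tail domain mutant and BMPR2 kinase domain mutant, with 2 libraries in each. How the mutants were introduced is not stated in the labels. BMPR2 is the type II receptor for bone morphogenetic proteins, a transmembrane serine/threonine kinase with a long cytoplasmic tail, and its mutations underlie heritable pulmonary arterial hypertension. The sample titles call the groups tail domain and kinase domain mutants, while the design text describes the cells as lacking these domains, with the empty vector as the reference for both. Neither was checked against the level of Bmpr2. Total counts in genes were 24936136 and 20291259 in the empty vector libraries. They were 22772673 and 19116082 in the tail mutant libraries, and 21465330 and 21933354 in the kinase mutant libraries. Between 14559 and 15071 genes had at least 1 count per library. The genes are given by Ensembl identifier, since the files do not pair identifiers with names, and their positions were not used here.

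On the first principal component of log2 CPM, which held 39.2% of the variance, the empty vector libraries scored -31.6 and -64.6 and the 4 mutant libraries between 18.9 and 27.7. The second component, with 30.9%, did not divide the mutant libraries by group. The replicates of the tail mutant scored 27.1 and -60.9 on it, and those of the kinase mutant -1.24 and 37.1. Pearson's r of log2 CPM across 12221 genes, which are not independent replicates, was 0.973 between the empty vector libraries, 0.947 between the tail mutant libraries and 0.967 between the kinase mutant libraries. Of the 15 pairs of libraries, the highest r was 0.982, between tail mutant replicate 1 and kinase mutant replicate 2. Between a tail and a kinase mutant library r ranged from 0.940 to 0.982, and between an empty vector and a mutant library from 0.925 to 0.968. The 0.968, between empty vector replicate 1 and tail mutant replicate 1, lay above the r between the tail mutant replicates. Tail mutant replicate 2 also differed in composition, since its 10 most counted genes took 16.0% of its counts against 19.9% to 22.1% in each of the other libraries.

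**Figure D1:**
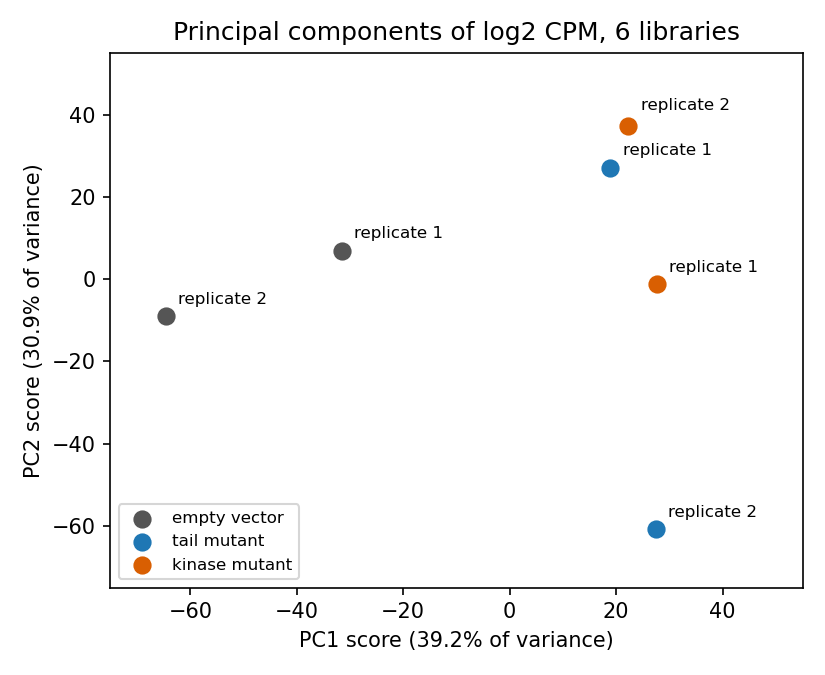
Scores of the 6 libraries on the first and second principal component of log2 CPM (axes: component scores, with the percentage of variance), 1 point per library coloured by group. The empty vector libraries lie at negative scores of the first component and the 4 mutant libraries at positive scores, while the tail mutant replicates lie at 27.1 and -60.9 on the second.

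The comparison of the tail mutant with empty vector asks how expression differs in cells with the tail domain mutant. The gene ENSRNOG00000006052 fell in the tail mutant, from 186 ± 73.9 CPM (SD, n = 2) in empty vector to 0.988 ± 0.107 CPM (SD, n = 2), and was lower in 2 of 2 tail mutant libraries than in both empty vector libraries. The change was -7.55 ± 0.40 (SE) on the log2 scale, with an adjusted p of 0.0109 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was the only gene of 12221 called by that test. In the 50 simulated sets without any difference between groups, edgeR called 0 to 4 genes in this comparison, with a mean of 0.94. A count of 1 thus lies within what unchanged groups gave. Only the number of calls was compared, so the simulations do not tell whether unchanged groups give a change of this size. ENSRNOG00000023337 stood at 99.4 ± 4.38 CPM in empty vector and 23.6 ± 2.76 CPM in the tail mutant (SD, n = 2), a log2 difference of -2.08 ± 0.18 (SE) that did not pass (adjusted p of 0.0752 in edgeR with Benjamini-Hochberg adjustment). Among genes higher in the tail mutant, the smallest p belonged to ENSRNOG00000013391, at 68.5 ± 6.25 CPM in empty vector and 178 ± 28.3 CPM in the tail mutant (SD, n = 2), which did not pass either (adjusted p of 0.254 in edgeR with Benjamini-Hochberg adjustment). ENSRNOG00000023337 passed with DESeq2 (Benjamini-Hochberg adjusted p of 2.29e-19), in edgeR with no filter (0.0129) and in edgeR without tail mutant replicate 1 (0.0498), the values over the alternatives ranging up to 0.583. ENSRNOG00000013391 passed with DESeq2 alone of the alternatives (Benjamini-Hochberg adjusted p of 3.92e-08, the others ranging up to 0.999).

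An unadjusted p below 0.05 in edgeR was reached by 446 genes higher and 600 genes lower in the tail mutant, together 1046 against 611 expected by chance. DESeq2 called 248 genes (93 higher and 155 lower), and limma-voom called 0, with 989 at an unadjusted p below 0.05. Without overlap between the libraries of the groups, 512 genes were at least 2-fold lower and 309 at least 2-fold higher by the fitted change. Libraries did not overlap in 37.8% of tested genes at any fold, where chance gives 33.3% for 2 libraries against 2. At least 8-fold apart in every library, 33 genes were lower and 2 were higher, together 35, of which 13 were found with a minimum of 5 CPM in the higher group.

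The edgeR call of ENSRNOG00000006052 against empty vector ended without tail mutant replicate 2 (adjusted p of 0.378 with Benjamini-Hochberg adjustment), without kinase mutant replicate 1 (0.0686) or replicate 2 (0.0710), with only the 4 libraries compared (0.0695) and with limma-voom (0.106). Over the alternatives the adjusted p ranged from 1.34e-67 with DESeq2 to 0.378 with edgeR, and the log2 change from -7.91 to -7.08. Single libraries also moved the counts. EdgeR called 2 genes without empty vector replicate 1 and 21, of which 16 were higher, without tail mutant replicate 1. The 1046 genes became 378 without empty vector replicate 2 and 2335 without tail mutant replicate 1. The number of genes at least 8-fold apart could only stay or rise when a library was left out, fewer libraries being a weaker criterion. The 35 genes became 192 without empty vector replicate 1 (20 higher and 172 lower). They became 167 without tail mutant replicate 1 (64 higher and 103 lower) and 81 without tail mutant replicate 2 (8 higher and 73 lower). Genes lower in the tail mutant thus outnumbered the others by far less without tail mutant replicate 1.

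The comparison of the kinase mutant with empty vector asks the same of cells with the kinase domain mutant. ENSRNOG00000006052 fell here too, to 0.221 ± 0.0316 CPM (SD, n = 2) from 4 and 5 counts, lower in 2 of 2 kinase mutant libraries than in both empty vector libraries. The change was -9.68 ± 0.46 (SE) on the log2 scale, with an adjusted p of 0.00595 in edgeR with Benjamini-Hochberg adjustment. It was again the only gene called by that test. The simulated sets without any difference gave 0 to 4 calls in this comparison, with a mean of 1.14, so this count too lies within that range. The size of the change was not compared with the simulations here either. Among genes higher in the kinase mutant, the smallest p belonged to ENSRNOG00000000827, at 48.6 ± 1.16 CPM in empty vector and 124 ± 0.552 CPM in the kinase mutant (SD, n = 2). Its log2 difference of 1.36 ± 0.15 (SE) did not pass (adjusted p of 0.224 in edgeR with Benjamini-Hochberg adjustment). ENSRNOG00000013391 stood at 200.3 ± 1.17 CPM in the kinase mutant (SD, n = 2), a log2 difference of 1.55 ± 0.19 (SE) that did not pass (adjusted p of 0.224 in edgeR with Benjamini-Hochberg adjustment). With DESeq2, alone of the alternatives, both passed, at Benjamini-Hochberg adjusted p-values of 1.23e-12 for ENSRNOG00000000827 and 3.43e-10 for ENSRNOG00000013391, the others ranging up to 0.994 for each. For ENSRNOG00000000827 the tail mutant also passed against empty vector with DESeq2 (8.07e-05) but not with edgeR (Benjamini-Hochberg adjusted p of 0.325). For ENSRNOG00000023337, at 85.4 ± 7.46 CPM in the kinase mutant (SD, n = 2), no difference from empty vector was detected (adjusted p of 0.668 in edgeR with Benjamini-Hochberg adjustment).

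**Figure D2:**
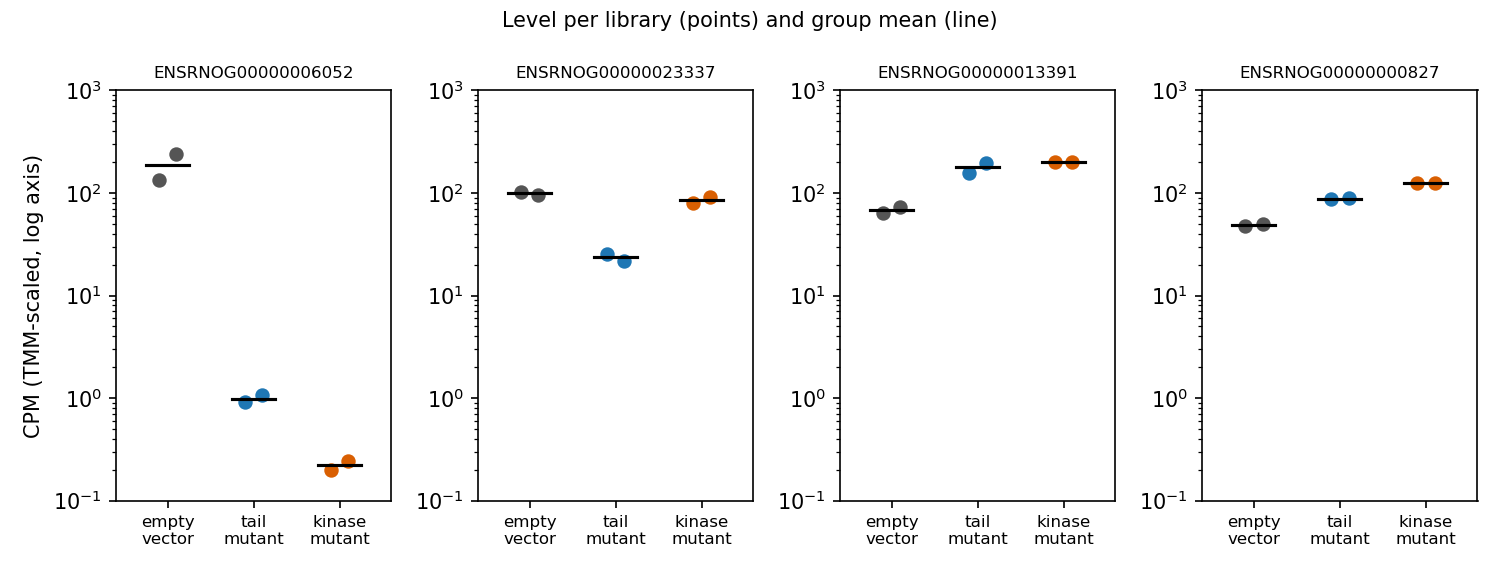
CPM (TMM-scaled, log axis common to the panels) of the 4 identifiers followed in the text, with 1 point per library and a line at the group mean of 2 libraries. ENSRNOG00000006052 stands at 186 CPM in empty vector and at 0.988 and 0.221 CPM in the tail and kinase mutants, and ENSRNOG00000023337 stands at 23.6 CPM in the tail mutant beside 99.4 and 85.4 CPM in empty vector and the kinase mutant.

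An unadjusted p below 0.05 in edgeR was reached by 642 genes higher and 680 genes lower in the kinase mutant, together 1322 against 611 expected by chance. DESeq2 called 361 genes (206 higher and 155 lower), and limma-voom called 0, with 1276 at an unadjusted p below 0.05. Without overlap of the libraries, 515 genes were at least 2-fold lower and 419 at least 2-fold higher by the fitted change. Libraries did not overlap in 50.7% of tested genes at any fold, against 33.3% by chance. At least 8-fold apart in every library, 32 genes were lower and 5 higher, together 37, of which 16 were found with a minimum of 5 CPM.

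The edgeR call of ENSRNOG00000006052 against empty vector ended without tail mutant replicate 1 (adjusted p of 0.0681 with Benjamini-Hochberg adjustment) or replicate 2 (0.0590), without kinase mutant replicate 1 (0.233) or replicate 2 (0.231), with only the 4 libraries compared (0.0662) and with limma-voom (0.241). Over the alternatives the adjusted p ranged from 8.26e-55 with DESeq2 to 0.241 with limma-voom, and the log2 change from -10.03 to -9.20. EdgeR called 2 genes without empty vector replicate 1. The 1322 genes became 492 without empty vector replicate 2 and 680 without kinase mutant replicate 1. The 37 genes, whose number again could only stay or rise, became 214 without empty vector replicate 1 (38 higher and 176 lower). They became 89 without kinase mutant replicate 1 (16 higher and 73 lower) and 98 without kinase mutant replicate 2 (43 higher and 55 lower). Without kinase mutant replicate 2 the directions were thus nearly balanced.

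Both mutants were compared with the same empty vector libraries, so their differences from it are alike by chance. Of the genes with an unadjusted p below 0.05 in both comparisons, 559 had the same direction (242 higher and 317 lower) and 2 the opposite. Independent lists of those sizes would share 23.4 higher and 33.4 lower genes, and simulated groups without any difference, compared with the same controls, shared between 102 and 160 genes with a mean of 135. The first value leaves out the shared controls and the second leaves out real effects, and part of the excess may come from the shared controls. The simulated libraries also differed gene by gene and independently. The simulated range, and the simulated r and covariance below, therefore do not describe libraries that differ in many genes together. Pearson's r of the log2 fold changes across genes, which are not independent replicates, was 0.752, against a mean of 0.496 in the simulations. The covariance was 0.522, against 0.132 simulated and 0.124 computed from the difference between the empty vector replicates. The difference of 0.391 between the observed and simulated covariance covers whatever set both mutants apart from the empty vector libraries beyond the spread between replicates, a shift particular to the empty vector cells included. ENSRNOG00000006052 was the only gene called by edgeR in both comparisons, where independent lists would share 8.18e-05 genes and the simulations shared between 0 and 1.

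**Figure D3:**
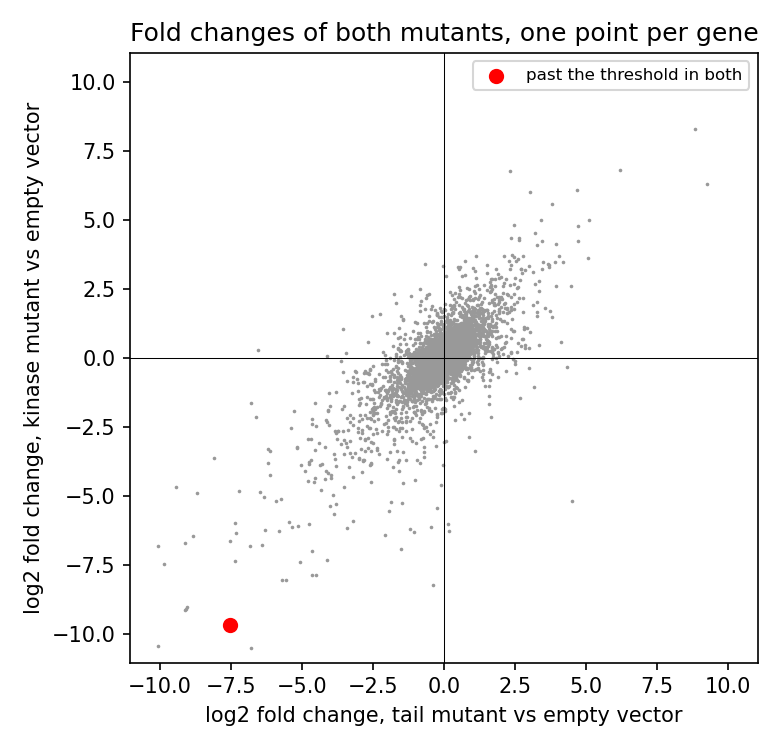
Log2 fold change against empty vector in the tail mutant (horizontal axis) and in the kinase mutant (vertical axis), 1 grey point for each of 12221 genes, with the gene past the threshold in both comparisons in red. The points lie along the diagonal (r = 0.752), and the red point, ENSRNOG00000006052, is at -7.55 and -9.68.

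At least 8-fold apart in every library, 16 genes were higher in both empty vector libraries than in all 4 mutant libraries, and 0 were lower. These genes ranged from 1.22 to 1549 CPM in empty vector, and the lower bound of their fold had a median of 13.7 and a maximum of 126, that of ENSRNOG00000006052. In 15 of the 16 the level was higher in empty vector replicate 2, which lies farther from the mutants on the first principal component, than in replicate 1. The median level was 10.8 CPM in replicate 2 and 3.89 CPM in replicate 1, and the 16 genes took 0.259% and 0.0627% of the counts. In 7 of them no mutant library exceeded 3 counts. Among the other 14 choices of 2 libraries, the highest number of such genes was 7, for tail mutant replicate 2 with kinase mutant replicate 1. The 16 genes became 6 with a minimum of 5 CPM, 136 without empty vector replicate 1 (13 of them lower in empty vector), 26 without empty vector replicate 2, 25 without tail mutant replicate 2 and 24 without kinase mutant replicate 1, fewer libraries being a weaker criterion. For the contrast of both mutants with empty vector, added after the data were examined, DESeq2 called 204 genes higher and 217 lower in the mutants. In edgeR this contrast called 4 genes, all lower in the mutants. It called 12, 2, 0, 0, 1 and 1 without empty vector replicates 1 and 2, tail mutant replicates 1 and 2 and kinase mutant replicates 1 and 2.

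**Figure D4:**
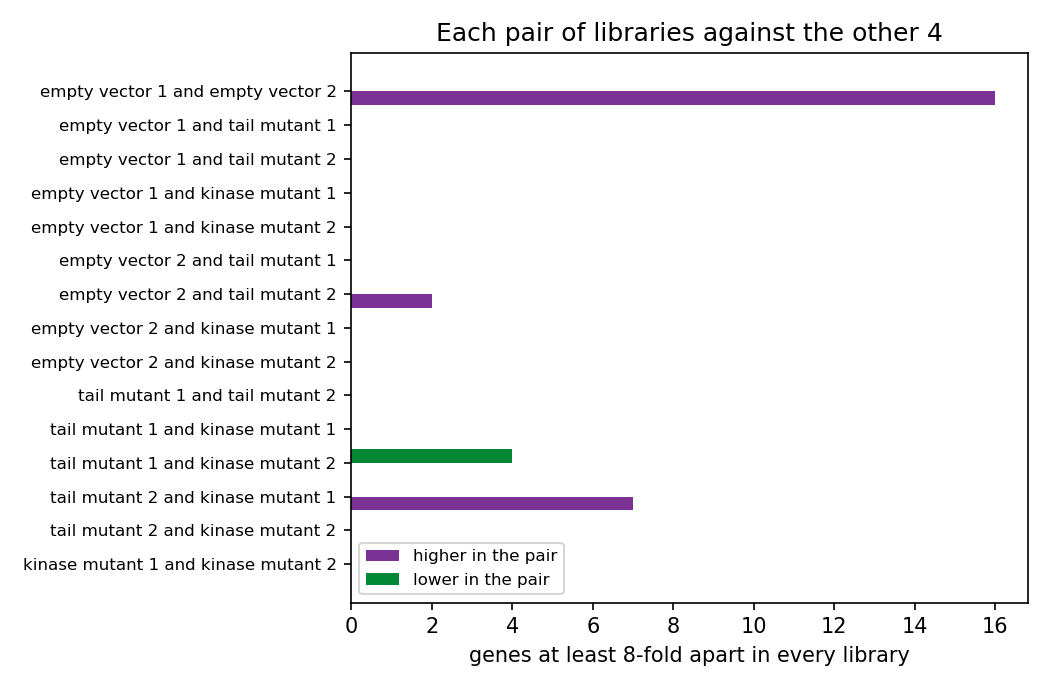
Number of genes at least 8-fold apart in every library (horizontal axis) for each of the 15 choices of 2 libraries against the other 4 (vertical axis), with genes higher in the 2 libraries and genes lower in them as separate bars. The choice of both empty vector libraries gives 16 genes, the choice of tail mutant replicate 2 and kinase mutant replicate 1 gives 7, and the others give 4 or fewer.

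The direct comparison of the tail mutant with the kinase mutant asks whether the mutants differ from each other. The smallest p belonged to ENSRNOG00000023337, at 23.6 ± 2.76 CPM in the tail mutant and 85.4 ± 7.46 CPM in the kinase mutant (SD, n = 2), a log2 difference of -1.86 ± 0.18 (SE) with an adjusted p of 0.381 in edgeR with Benjamini-Hochberg adjustment, which did not pass. DESeq2 called this gene with a Benjamini-Hochberg adjusted p of 1.09e-14, the values over the alternatives ranging up to 0.999. ENSRNOG00000006052 was 2.13 ± 0.51 (SE) higher in the tail mutant on the log2 scale, which did not pass (adjusted p of 0.926 in edgeR with Benjamini-Hochberg adjustment). ENSRNOG00000000827, at 88.3 ± 1.17 CPM in the tail mutant and 124 ± 0.552 CPM in the kinase mutant (SD, n = 2), did not pass (adjusted p of 0.926 in edgeR with Benjamini-Hochberg adjustment). For ENSRNOG00000013391 the log2 difference was -0.17 ± 0.18 (SE).

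Between the mutants edgeR called 0 genes, with 448 at an unadjusted p below 0.05 (184 higher and 264 lower in the tail mutant), against 611 expected by chance. DESeq2 called 12 genes (2 higher and 10 lower in the tail mutant), and limma-voom called 0, with 392 at an unadjusted p below 0.05. Without overlap of the libraries, 281 genes were at least 2-fold lower and 145 at least 2-fold higher in the tail mutant by the fitted change. Libraries did not overlap in 30.0% of tested genes at any fold, against 33.3% by chance. At least 8-fold apart in every library, 1 gene was lower and 0 were higher in the tail mutant. This count, too, could only stay or rise when a library was left out. It became 85 (49 higher and 36 lower) and 14 (2 higher and 12 lower) without tail mutant replicates 1 and 2. It became 21 (8 higher and 13 lower) and 14 (0 higher and 14 lower) without kinase mutant replicates 1 and 2. Without tail mutant replicate 1 the 448 genes became 2349, with 0 called by edgeR. They became 297 without empty vector replicate 2, 258 without tail mutant replicate 2 and 266 without kinase mutant replicate 1.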

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

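The share of reads in no annotated gene lies outside the comparisons above and was higher in each of the 4 mutant libraries than in either empty vector library. It was 16.9% ± 0.890 in the tail mutant and 16.7% ± 0.893 in the kinase mutant, against 15.4% ± 0.0159 in empty vector (SD, n = 2), as a percentage of the total over all rows of a file. Among uniquely aligned reads alone the share was 23.0% and 25.3% in the tail mutant, 22.6% and 23.9% in the kinase mutant, and 22.5% and 21.3% in empty vector, so that the nearest mutant and empty vector libraries were almost level. The difference between groups was not tested, and no biological explanation was tested.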

How the results depend on the processing

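The crossed replicate block, and every value for both mutants together, were added after the data were examined. The log2 changes of the 4 identifiers had the same sign under all alternatives run, in all 3 comparisons. They were picked by a small p in these data, and the alternatives refit the same counts or leave out 1 library. For the comparisons they were picked from, the same sign was therefore nearly fixed in advance. The number of genes called depended on the tool: DESeq2 gave 248 for the tail mutant, 361 for the kinase mutant, 12 between the mutants, 144 shared by both mutants and 421 for both mutants together, and limma-voom gave 0, 0, 0, 0 and 1. All DESeq2 calls had an unadjusted p below 0.05 and the same sign in edgeR. Both tools were fitted to the same counts and groups, so this is no independent support for those calls. In the same order, edgeR with no filter gave 9, 2, 0, 2 and 49 (the last with 5 higher and 44 lower in the mutants). The replicate number as a block gave 2, 2, 0, 2 and 2, and the replicate block with the kinase mutant numbers exchanged gave 2, 2, 0, 2 and 18. Using only the 4 libraries compared gave 0 for each mutant, 0 between them and 0 shared, with 882, 1826 and 297 genes at an unadjusted p below 0.05 in the 3 comparisons. RLE size factors, the stricter filter and the 1.2-fold test gave the reported counts of 1, 1, 0, 1 and 4. The labels do not say that the numbers pair the libraries, and the replicate differences correlated by 0.124 (empty vector and tail), -0.131 (empty vector and kinase) and -0.353 (tail and kinase). Leaving out 1 library gave 0 to 21 genes for the tail mutant, 0 to 2 for the kinase mutant, 0 between the mutants, 0 to 2 shared and 0 to 12 for both mutants together. An arm left with 1 library is assumed to vary like the others. The correlation of the fold changes was 0.752 as reported, 0.625 with no filter and 0.626 as Spearman's rho, and ranged from 0.575 (without tail mutant replicate 1) to 0.831 (without empty vector replicate 1). The cause of these differences was not tested. Thinned to the lowest total, 15 in place of 16 genes stood at least 8-fold apart between empty vector and all mutant libraries. The totals in genes were close beforehand, so thinning could hardly change this count and does not show what depth limits. The planned list tests were not run, since the tables used here pair no identifier with a name.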

Other observations

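The tests by other choices of libraries and by the share of reads in no gene were chosen after the results were seen.

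In 16 genes both empty vector libraries were at least 8-fold above all 4 mutant libraries. Totals in genes ranged only from 19116082 to 24936136, too narrow a range for unequal depth to make an 8-fold difference in CPM. After every library was thinned to the lowest total, 15 genes were found. Thinning over that range could hardly change the count, so it adds little. When libraries were scaled by their totals without the 10 most counted genes, 20 were found. In each library its 10 most counted genes took 16.0% to 22.1% of the counts. Leaving out such a share changes the scale too little to make or remove an 8-fold difference, so this result decides nothing. Of the 15 choices of 2 libraries against 4, 1 gave as many genes, the real one with 16 against 7 for the highest other, and in a fit of those 2 sets edgeR called 3 genes for the real choice against 2 for the highest other, again 1 of 15. So few choices cannot give a share under 0.05. By genes with an unadjusted p below 0.05 the real choice was not the highest, with 1427 against 1584 for tail mutant replicate 2 with kinase mutant replicate 1 and 1364 for empty vector replicate 2 with tail mutant replicate 2. The hypothesis that the low level of these transcripts follows from the BMPR2 mutants, and the alternative that the empty vector cells differ for another reason, both stay open, since the design holds 1 control and no Bmpr2 level was read.

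Of the 3 ways to divide the 4 mutant libraries into pairs, the one across their labels separated most genes: tail mutant replicate 1 and kinase mutant replicate 2 differed at least 8-fold from the other pair in 23 genes, 21 of them lower, against 1 gene for tail against kinase as labelled and 1 for the remaining division. After thinning 22 genes were found, though here too the totals were too close for unequal depth to make such a difference or for thinning to remove it. The 2 pairs were not equally alike, with a Pearson's r of log2 CPM of 0.982 in the first and 0.955 in the other. Kinase mutant replicate 1 reached 0.969 with tail mutant replicate 1 and 0.967 with kinase mutant replicate 2. For tail mutant replicate 2, 0.955 was the highest r with any library. An exchange of a tail and a kinase library is a candidate explanation that stays open: it would leave the labelled division no stronger than the remaining one, and these had 10 and 7 genes at least 4-fold apart (exact binomial test, two-sided, p = 0.629, over genes that are not independent). Single genes followed the labels. ENSRNOG00000000827 stood at 87.5 and 89.1 CPM in the tail mutant and 124.8 and 124.1 CPM in the kinase mutant. ENSRNOG00000006052 had 20 and 22 counts in the tail mutant against 4 and 5 in the kinase mutant. Both were chosen by a small p against empty vector. Such a choice favours genes whose labelled replicates agree, so these genes are not independent of the labels. ENSRNOG00000023337, picked from tail against kinase itself, stood at 25.5 and 21.6 CPM against 80.1 and 90.7 CPM. At an unadjusted p below 0.05 in edgeR there were 1358 genes for the division across labels. There were 448 for the labelled one and 282 for the remaining one, both under the 611 expected by chance. In the fits of these last 2, the division across labels enters the spread between replicates and lowers such counts. They therefore cannot show whether the labels separate. The 3 genes are few and were all picked by tests that use the labels, so they do not exclude an exchange. A library property seen in reads outside genes also stays open, since the share of reads in no gene was 16.2% and 16.1% in the first pair and 17.5% and 17.4% in the other, a gap of 1.13 percentage points, and no label gives a batch.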
